A study of Mus musculus with 2 samples.

How the data were processed

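Chromatin immunoprecipitation followed by sequencing (ChIP-seq) against dimethylated lysine 4 of histone H3 (H3K4me2), a mark found at promoters and enhancers, was carried out on limbs of mouse embryos at day 12.5 of development. There were 2 libraries, both of the same strain, tissue and age, which form 1 group. Per the labels, replicate 1 came from the limbs of 88 embryos and replicate 2 from those of 68 embryos, male and female together, and fragments of 300 to 500 bp were selected in both. The labels give the same donor identifier to both pools, so the spread between them is a spread between pools of embryos of one strain.

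The deposited data are 4 peak lists on the mouse assembly mm10: a list for each library, a list called on both libraries pooled, and a list of replicated peaks. Per the file headers of the accompanying text files, the lists were made from filtered alignments together with a further file whose role is not stated, and the replicated list was made from the pooled list and the lists of both libraries. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries a fold enrichment, a linear ratio that the authors computed, and it is the authors' own value throughout. The authors also deposited the −log10 of a p-value and of a q-value for each peak, and the position of its summit. The smallest −log10 p in any list is 2.00, so weak calls were kept in the deposited lists. Fold enrichment was used only to describe, rank or filter peaks within a list. The lists hold no read counts, so the depth of each library is unknown, and no interval or limit that needs it is given.

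Coordinates of the lists were compared with the lengths of the chromosomes of assembly GRCm38.p6, and all peaks on chromosomes 1 to 19, X and Y lay within them. Only these chromosomes entered the comparisons. Genes were the 21938 protein-coding genes of the GENCODE M21 basic set on the same assembly, and gene symbols in lists were matched to it directly or through synonyms of the RefSeq gene table of that assembly. A promoter peak was a peak within 1 kb of any annotated transcript start of a gene. Bases covered were counted within 5 kb on either side of the 5′ start of each gene. A distal peak had its midpoint more than 2.5 kb from any start of these genes, and was assigned to the gene with the nearest start within 500 kb. Starts of non-coding genes were not used, so peaks at them can count as distal or intergenic. A promoter was CpG-rich when the 500 bp on each side of the most 5′ start had an observed to expected CpG ratio of at least 0.6 and a GC share of at least 0.5. Peaks within 1 kb of each other were merged into regions, and the widest 5% of the merged regions that overlapped a promoter, by covered bases, were called broad.

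The shared peaks of the libraries were counted with an overlap of at least 1 bp and compared with 100 random placements of the peaks on the same chromosomes outside assembly gaps. A one-sided permutation p from these cannot go below 0.0099 and a two-sided one below 0.02. The same placements gave the background for the genomic classes, where each peak midpoint was assigned to promoter, exon, intron or intergenic sequence in that order. A set of 20 gene lists, 28 loci and 28 consensus motifs, the tests, the alternatives and the rule for the genes to be named were fixed before the data were examined. Shares of list members were compared with those of all other protein-coding genes by Fisher's exact test, two-sided. Medians of covered bases were compared with 10000 random lists of the same size. Mean numbers of distal peaks were compared with 10000 random lists matched on deciles of domain length, the stretch of genome nearest to a gene's starts. Locus coverage was compared with up to 10000 random windows of the same length on the autosomes and X, with at most 5% assembly gaps and the same number of gene starts within 1. Motifs were searched on both strands in 1000-bp windows around the midpoints of distal peaks. The background windows were centred 3 kb away, touched no pooled peak and were sampled to the same GC distribution in bins of 2%. Presence of promoter peaks in only one library was tested with an exact binomial test of the discordant genes. The p-values of lists, loci and motifs were adjusted by the Benjamini-Hochberg method within their family, over 20 lists, 28 loci or 28 motifs. Those of the replicate overlap, the genomic classes, the CpG-rich promoters and the discordant genes over all genes were not adjusted. Permutation p-values against random lists cannot go below 0.0002.

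The genes to be named were, for each list, the 3 members with most bases covered around the start and up to 3 members without a promoter peak, taken alphabetically. Genome-wide they were the 10 genes with most distal peaks, the genes in the 10 widest merged regions and those nearest to the 5 strongest peaks. Ties were resolved by distal peaks and then alphabetically. Of the lists, the limb patterning list had 46 of its 47 symbols matched and the neuronal list 37 of 38, and all other lists were matched in full.

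Alternatives were a stricter threshold (−log10 q of at least 5), other overlap rules, promoter windows of 500 bp and 2.5 kb, the most 5′ start only, windows of 2.5 and 10 kb for covered bases, distal peaks over 10 kb away, merging within 3 kb, the widest 2% of regions, motif windows of 400 bp, and other backgrounds. The pooled list and each library's own list also replaced the replicated list. Comprehensive GENCODE transcripts, matching of lists on deciles of promoter CpG content, and all alternatives for the density of peaks on chromosome X were added after seeing the data. Values given as mean ± SD with n = 2 come from the 2 libraries' own lists. These lists hold more weak peaks than the replicated list, so their means can lie above or below its value. Wilson 95% intervals of shares of peaks served only to judge whether a share moved under an alternative.

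The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. The functions were tested on simulated data. For the replicate overlap, 71.1% of 52089 simulated peaks were found shared where 69.9% had been planted, the rest being chance overlaps. For promoter marking over 21938 genes, 4.5% of unchanged lists passed an unadjusted 0.05, and 96% of lists of 30 genes planted at 95% marked did. For covered bases and distal peaks the shares of unchanged lists past 0.05 were 3% and 7%, and all lists planted at 3 times the value were found. For loci, 2% of 100 unchanged windows passed. For broad regions, all planted members were found. For motifs, the 3 planted consensus sequences were found in 2481 windows, and 1 of the others, PITX, passed the adjusted threshold without having been planted.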

Results

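H3K4me2 was profiled by ChIP-seq in mouse limbs at embryonic day 12.5, when the digits are being laid down as cartilage condensations. There were 2 libraries of 1 group, replicate 1 from 88 pooled embryos and replicate 2 from 68, and no other tissue, stage or input sample was analysed here. On chromosomes 1 to 19, X and Y the list of replicate 1 held 52089 peaks over 52.0 Mb and that of replicate 2 held 51961 peaks over 54.4 Mb. The pooled list held 61286 peaks over 64.2 Mb, and the replicated list, which is used below unless another is named, held 39478 peaks over 58.1 Mb. The median peak width was 578 bp in replicate 1, 629 bp in replicate 2 and 1068 bp in the replicated list. The lists give no read counts, so the depth of the libraries is unknown.

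The first question was how far the pools of embryos gave the same peaks. Of the peaks of replicate 1, 80.1% were overlapped by a peak of replicate 2, and of those of replicate 2, 77.6% by a peak of replicate 1 (mean 78.8%). These are the 2 directions of 1 comparison, so they give no spread between replicates. Randomly placed peaks overlapped 4.35% and 4.34% of them. Of all bases covered in either library, 76.1% were covered in both, against 1.13% for random placement (permutation p = 0.0099 for each of the 3 measures, one-sided, the smallest that 100 placements allow). Sharing followed peak strength, measured by the authors' fold enrichment. In the weakest decile 43.7% of the peaks of replicate 1 and 38.5% of those of replicate 2 were shared (mean 41.1%). In the 4 strongest deciles of both lists all peaks were. Peaks without a counterpart were narrow, with a median width of 228 bp in replicate 1 and 241 bp in replicate 2, against 827 and 924 bp for shared peaks. Most of them lay more than 2.5 kb from any start of a protein-coding gene: 84.2% and 82.1% were distal, against 52.9% and 53.0% of shared peaks. Of the peaks centred within 1 kb of a start of a protein-coding gene, 2.93% in replicate 1 and 3.91% in replicate 2 had no counterpart. The 10000 strongest peaks of each list, ranked within that list, overlapped at 84.6% (mean of the 2 directions).

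**Figure D1:**
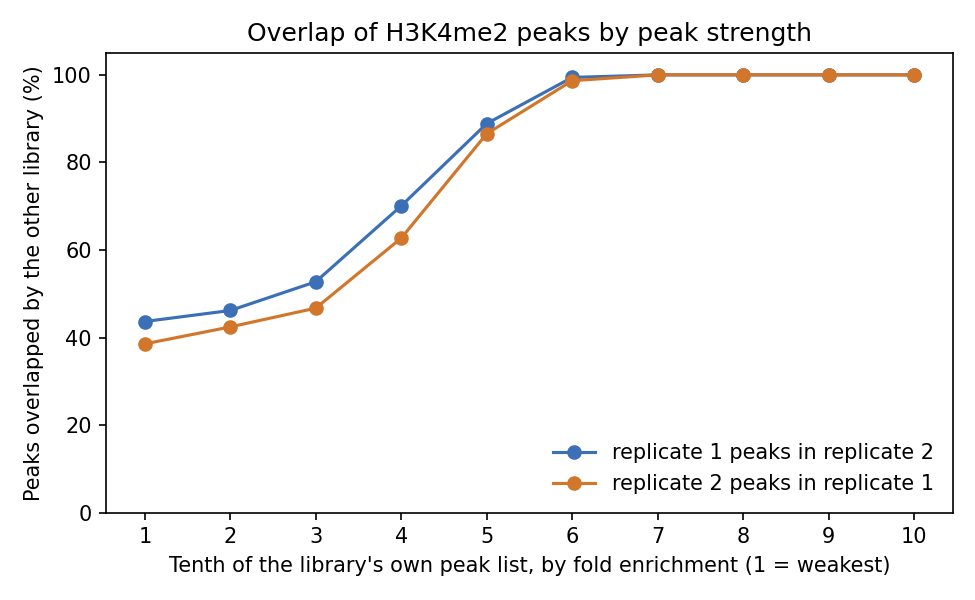
Share of each library's peaks (y axis, %) overlapped by at least 1 bp by a peak of the other library, by decile of its own list ranked by fold enrichment (x axis, 1 is the weakest). Each line is one library, and the share is 43.7% and 38.5% in the weakest decile and 100% in the strongest 4.

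The replicated list was a subset of the pooled list, with 64.4% of its peaks. At least 50% of the length was covered by replicate 1 in 88.2% of the replicated peaks and by replicate 2 in 92.0%. The pooled peaks that were kept had a median fold enrichment of 10, and those left out 2.57. A peak of each library met an overlap of 50% of either peak in 36323 pooled peaks, and all of these were in the replicated list. A further 3155 replicated peaks (7.99%) did not meet that rule.

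The next question was where the mark lies in the genome. Promoters held 35.5% of the midpoints of replicated peaks (30.7% ± 0.23 in the libraries' own lists, SD, n = 2), which was 16.1 times the share of randomly placed peaks. Exons held 4.42% (4.59% ± 0.13), 1.72 times the random share. Introns held 29.4% (34.3% ± 0.039) and intergenic sequence 30.7% (30.5% ± 0.32), below the random shares of 37.5% and 57.7%. Each of these differences had a permutation p of 0.02, the smallest that 100 placements allow in a two-sided test. For introns the difference was lost with promoter windows of 500 bp (37.8% against 38.1%) and with the pooled list (37.8% against 37.6%). The strongest peaks by the authors' fold enrichment lay at gene starts. The first was on chromosome 12 from 76709030 to 76711384, with a 73.3-fold enrichment, 184 bp from the start of Sptb, which encodes a spectrin of the membrane skeleton. The next were nearest to Cabp1 (70.0-fold), Egr1 (69.0-fold), which encodes an immediate early transcription factor, Tysnd1 (66.7-fold) and Jph4 (66.7-fold).

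Of 21938 protein-coding genes, 14729 had a promoter peak, or 67.1% (67.5% ± 0.14 in the libraries' own lists, SD, n = 2). Promoter base composition divided the genes. CpG-rich promoters were marked in 9994 of 10086 genes, or 99.1% (99.1% ± 0.028), and other promoters in 4735 of 11852, or 40% (40.6% ± 0.23), an odds ratio of 163 with a p too small for the exact test to return as a number. CpG content was taken at the most 5′ start, while a peak at any start of the gene counted. With peaks at the most 5′ start only, 99.1% of CpG-rich and 37.0% of other promoters were marked. Over deciles of promoter CpG content the marked share went from 3.78% in the lowest decile to 99.5% in the highest, with 52.4% in decile 4 and 87.2% in decile 5. In the libraries' own lists, 14661 genes had a promoter peak in both, 126 only in replicate 1 and 168 only in replicate 2.

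**Figure D2:**
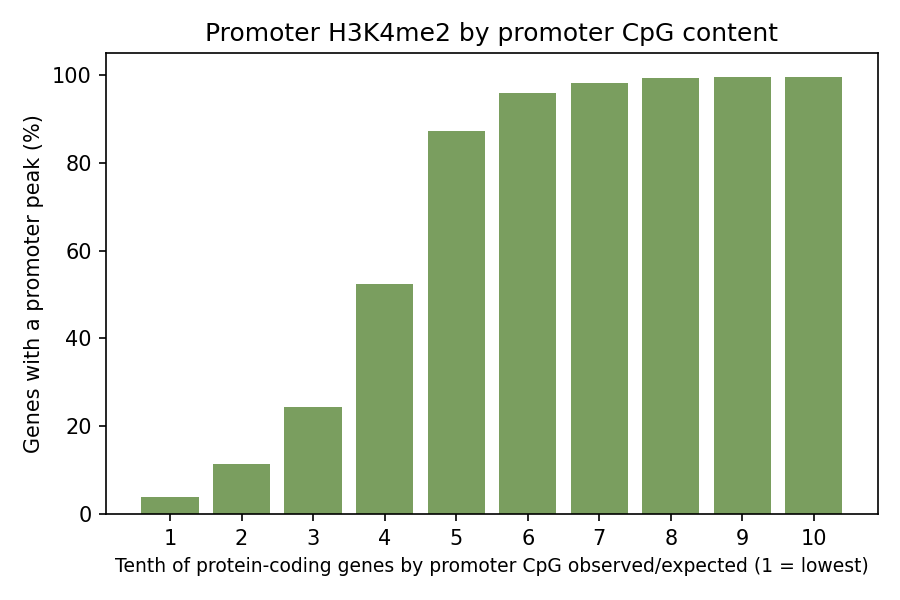
Share of protein-coding genes with a replicated peak within 1 kb of a start (y axis, %) by decile of the observed to expected CpG ratio around the most 5′ start (x axis, 1 is the lowest). The bars go from 3.78% in the lowest decile to 99.5% in the highest.

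Gene lists were then compared to ask which cell types and programmes of the limb carry the mark at their promoters. All 46 limb bud patterning genes had a promoter peak, as did all 39 Hox genes and all 22 joint and digit-interzone genes. So did all 30 housekeeping genes and all 30 cell cycle genes. The share was 93.8% of 32 chondrogenic genes (92.2% ± 2.2, SD, n = 2), 93.1% of 29 tendon and connective tissue genes (93.1% ± 0), 93.1% of 29 genes of the apical ectodermal ridge and limb ectoderm (94.8% ± 7.3) and 96.2% of 79 ribosomal protein genes (96.2% ± 0). Of 37 neuronal genes 94.6% were marked (95.9% ± 1.9). These 10 lists lay above the other genes, of which 67.0% to 67.1% were marked, with adjusted p from 1.9e-09 to 0.003 in Fisher's exact test. Below them lay 4 lists of other tissues and lineages, which were blood cell genes with 13.3% of 30 marked (15.0% ± 2.4), liver genes with 14.7% of 34 (13.2% ± 2.1), gut and lung epithelium genes with 26.7% of 30 (31.7% ± 7.1) and germ cell genes with 11.8% of 34 (13.2% ± 2.1). Their adjusted p in the exact test ranged from 3.1e-10 to 1.7e-05. Chemosensory receptor genes also lay below, with 6 of 1435 marked, 0.418% (0.383% ± 0.049).

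For 5 lists the share did not pass the threshold, with adjusted p from 0.15 to 1 in Fisher's exact test. It was 50% of 20 osteoblast genes (50% ± 0, SD, n = 2), 66.7% of 36 myogenic genes (72.2% ± 0), 66.7% of 30 endothelial genes (71.7% ± 2.4), 77.3% of 22 Schwann cell and neural crest genes (84.1% ± 3.2) and 53.3% of 30 heart genes (53.3% ± 4.7). The heart list fell below background with promoter windows of 500 bp (46.7%, adjusted p = 0.039, exact test). Against random lists matched on CpG-rich and other promoters the same 10 lists lay above and the same 5 below. Against random lists matched on deciles of CpG content, an alternative added after seeing the data, 4 lists stayed above in the permutation test, which were the limb patterning (adjusted p = 0.015), chondrogenic (adjusted p = 0.0013), tendon (adjusted p = 0.002) and Hox lists (adjusted p = 0.015). The liver, gut and lung, germ cell and chemosensory lists stayed below, and the blood cell list did not (adjusted permutation p = 0.35). At 100%, the joint, housekeeping and cell cycle lists could not have passed on deciles. Random lists reached 100% too often (unadjusted permutation p = 0.13, 0.51 and 0.80).

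Single genes of the lists show which members carried no promoter peak. In the chondrogenic list these were Cytl1 and Snorc, in the tendon list Kera and Tnmd, which encodes tenomodulin, a late marker of tendon cells, and in the ectoderm list the keratin genes Krt14 and Krt15. In the osteoblast list they included Bglap and Bglap2, which encode osteocalcins, and Col10a1, the collagen of hypertrophic cartilage, and the most covered members, all with promoter peaks, were the transcription factor genes Satb2 (6729 of 10001 bases), Sp7 (5267) and Atf4 (5174). In the myogenic list Acta1, Cacna1s and Chrna1, genes of differentiated muscle, had none, and Six1 (7962 bases), Lbx1 (6723) and Eya4 (5026), which act early in muscle precursors, were among the most covered. Endothelial members without one included Cdh5, Emcn and Lyve1, while Fli1 had 9214 bases covered, Prox1 7037 and Dll4 6364. Among blood cell genes Alas2, Cd68 and Csf1r had no promoter peak, though 4364 bases within 5 kb of Cd68 were covered, and Epor (2840) and Nfe2 (2414) had one. Schwann cell and neural crest genes without a promoter peak included Cdh19, Dct and Phox2b, and the most covered were Tfap2b (6298), Egr2 (5268) and Erbb3 (4983). Neurod6 and Slc17a6 were the neuronal members without one, and Isl1 (7489), Nefm (5032) and Rbfox3 (4268) the most covered. In the heart list Bmp10, Csrp3 and Mybpc3 had none, and Tbx18 (8185), Hand1 (7163) and Gata6 (5986) were the most covered.

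The liver genes without a promoter peak included Alb, Afp and Ahsg, which encode serum proteins, and the 3 most covered members were the transcription factor genes Cebpa (4319), Foxa3 (3332) and Foxa2 (2749). Those of the gut and lung list included Cdh17, Cela1 and Cpa1, and Lgr5 (3869) and Foxa1 (3646) led that list, followed by Sftpc (3260), which had no promoter peak of its own. Acr, Bmp15 and Ddx4 were germ cell genes without one, and Tdrd1 (2709), Gdf9 (2431, with no promoter peak) and Rec8 (1868) had most bases covered. Of the ribosomal protein list only Rpl10l, Rpl39l and Rpl3l lacked a promoter peak, and Rps11 (7288), Rpl35 (6832) and Rpl23a (6487) had most bases covered. Tubb5 (7886), Polr2a (6151) and Eef2 (5916) led the housekeeping list, and Ccnd2 (8785), Ccnd1 (7535) and Mcm2 (5801) the cell cycle list. Of the chemosensory genes, Olfr1, Olfr10 and Olfr1000 had none, and Vmn1r4 had 2900 bases covered, Olfr94 had 1282 and Olfr1342 had 803.

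**Figure D3:**
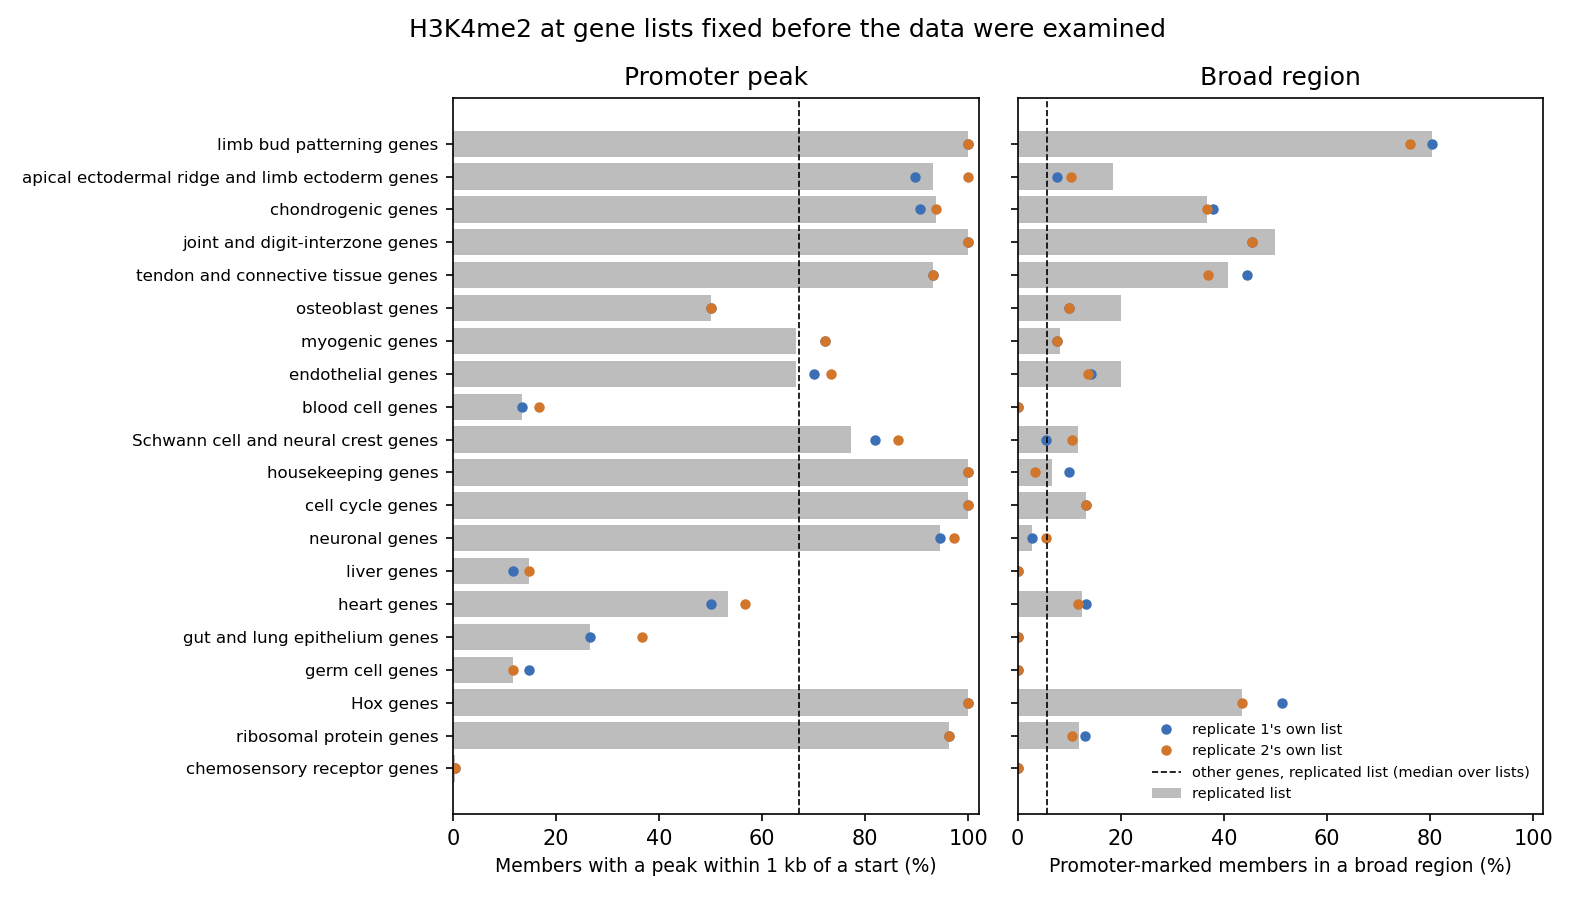
Left, share of each gene list's members with a peak within 1 kb of a start (x axis, %). Right, share of the promoter-marked members that lie in a broad region (x axis, %). Bars give the replicated list, points each library's own list, and the dashed line the other genes. Limb bud patterning genes reach 100% on the left and 80.4% on the right, and neuronal genes 94.6% and 2.86%.

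The breadth of the mark was measured by the bases covered around gene starts, with each list compared with random lists. The median limb patterning gene had 7793 of the 10001 bases around its start covered (7643 ± 157 bp in the libraries' own lists, SD, n = 2), against 1970 for random lists. Hox genes had a median of 6145 bp (5585 ± 590), joint genes 5490 bp (5058 ± 192), tendon genes 5032 bp (4729 ± 502), chondrogenic genes 4545 bp (4090 ± 167) and ectoderm genes 3647 bp (3189 ± 214). Lmx1b, the dorsal selector gene of the limb, had all 10001 bases covered (10001 ± 0, SD, n = 2), as did Pitx1, the hindlimb gene (9938 ± 14), and Hand2, a posterior patterning gene (9729 ± 238). In the connective tissue list Ebf3 had 10001 bases (9806 ± 119), Six2 9946 (9594 ± 152) and Pdgfra 9477 (9476 ± 122). Chondrogenic genes were led by Foxc1 with 9040 bases (8842 ± 152), Nkx3-2 with 8873 (8023 ± 515) and Sox9, the master regulator of cartilage, with 8521 (8010 ± 109). The joint list was led by Osr2 with 8507 (8236 ± 138), Wnt5a with 7839 (7526 ± 298) and Osr1 with 7792 (7618 ± 23). Cldn6 had 7298 bases (6154 ± 266), Fgf9 5764 (5696 ± 27) and Wnt6 5736 (5105 ± 191) in the ectoderm list, and Hoxa10, Hoxa11 and Hoxa13 each had 10001.

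Housekeeping genes (3633 bp, 3333 ± 156), cell cycle genes (3732 bp, 3557 ± 115) and ribosomal protein genes (3130 bp, 2873 ± 16) also lay above random lists. All 9 lists above had an adjusted permutation p of 0.0004. The random lists do not copy the clustering of the Hox genes, whose windows can overlap, so the test counts some covered bases of that list more than once. In every list the windows also take in bases nearer to the start of another gene, and random lists were not matched on gene density. Cldn6, with 7298 bases covered, had a domain length of 3.48 kb, and Rpl35, with 6832, one of 4.88 kb. The neuronal list, with 2488 bp (2214 ± 119), did not pass the threshold against random lists (adjusted permutation p = 0.15). Nor did the endothelial (2255 bp, 2026 ± 32), Schwann cell and neural crest (2152 bp, 1885 ± 89), myogenic (1597 bp, 1359 ± 84), osteoblast (803 bp, 576 ± 165) and heart lists (745 bp, 703 ± 68), with adjusted permutation p from 0.086 to 0.70. The medians of the blood cell, liver, gut and lung, germ cell and chemosensory lists were 0 bp, with adjusted permutation p from 0.0004 to 0.025. These 5 calls were lost against random lists matched on CpG-rich and other promoters, where the median was often 0 as well (adjusted permutation p from 0.17 to 1). As 0 bp is the lowest possible median, that matched test could not have called any of the 5 lists below.

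Broad regions were the widest 703 merged regions at promoters, each with at least 5650 covered bases, and held 850 genes. Of promoter-marked limb patterning genes 37 of 46, or 80.4% (78.3% ± 3.1, SD, n = 2), lay in one, against 5.54% of other marked genes, with an adjusted p of 9.3e-37 in Fisher's exact test. The share was 50% of joint genes (45.5% ± 0), 43.6% of Hox genes (47.4% ± 5.4), 40.7% of tendon genes (40.7% ± 5.2) and 36.7% of chondrogenic genes (37.3% ± 0.89), with adjusted p between 1.1e-10 and 1.8e-06 in the exact test. With peaks within 3 kb merged the share of Hox genes was 69.2%. Of the 17 broad Hox genes 16 lie in 3 merged regions, and 8 of the Hox genes are also in the limb patterning list, so the exact test counts as separate genes some that share a region. It was 18.5% of ectoderm genes (9.02% ± 1.9), with an adjusted p of 0.059 in the exact test, and passed the threshold when peaks within 3 kb were merged (33.3%) or the pooled list was used (20.7%). It was 14.8% at the stricter threshold, 10.3% without replicate 1 and 7.69% without replicate 2, with adjusted p from 0.19 to 1 in the exact test. Of neuronal genes 1 of 35 lay in a broad region (4.21% ± 1.9 in the libraries' own lists, SD, n = 2), and of housekeeping genes 2 of 30 (6.67% ± 4.7), with adjusted p of 0.96 for both in the exact test. The share was 20% for endothelial (14.0% ± 0.46, SD, n = 2) and osteoblast genes (10% ± 0), 13.3% for cell cycle (13.3% ± 0), 12.5% for heart (12.5% ± 1.1), 11.8% for ribosomal protein (11.8% ± 1.9) and Schwann cell and neural crest (8.04% ± 3.5), and 8.33% for myogenic genes (7.69% ± 0). None of these passed (adjusted p from 0.073 to 0.96, exact test), but the ribosomal protein list did with the pooled list and without replicate 2 (13.2% in both), and the cell cycle list when peaks within 3 kb were merged (20%). No marked blood cell, liver, gut and lung, germ cell or chemosensory gene lay in one.

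The widest region was on chromosome 6 from 52199775 to 52269388 and held the starts of Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10, Hoxa11, Hoxa13 and the gene model Gm28308. It had 68624 bases covered (67493 ± 304, SD, n = 2). The next was on chromosome 2 from 74647651 to 74702391, with Evx2, Hoxd9, Hoxd10, Hoxd11, Hoxd12 and Hoxd13 and 52369 bases covered (50916 ± 756). The one after it was on chromosome 15 from 102942419 to 102985303, with Hoxc9, Hoxc10 and Hoxc11 and 41030 bases covered (38990 ± 1008). The other 7 of the 10 widest each held the start of 1 gene. They were Ebf3 on chromosome 7 (26112 bases, 24549 ± 472), Hand2 on chromosome 8 (25200, 24527 ± 368), Zfhx3 on chromosome 8 (25056, 24142 ± 200), Nr2f2 on chromosome 7 (24810, 23324 ± 954), Lmx1b on chromosome 2 (22968, 21766 ± 18), Bahcc1 on chromosome 11 (20892, 19548 ± 304) and Rara, the retinoic acid receptor alpha gene, on chromosome 11 (20148, 19102 ± 488). The region at Zfhx3 lay at a start other than its most 5′ one, around which 3621 bases were covered.

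**Figure D4:**
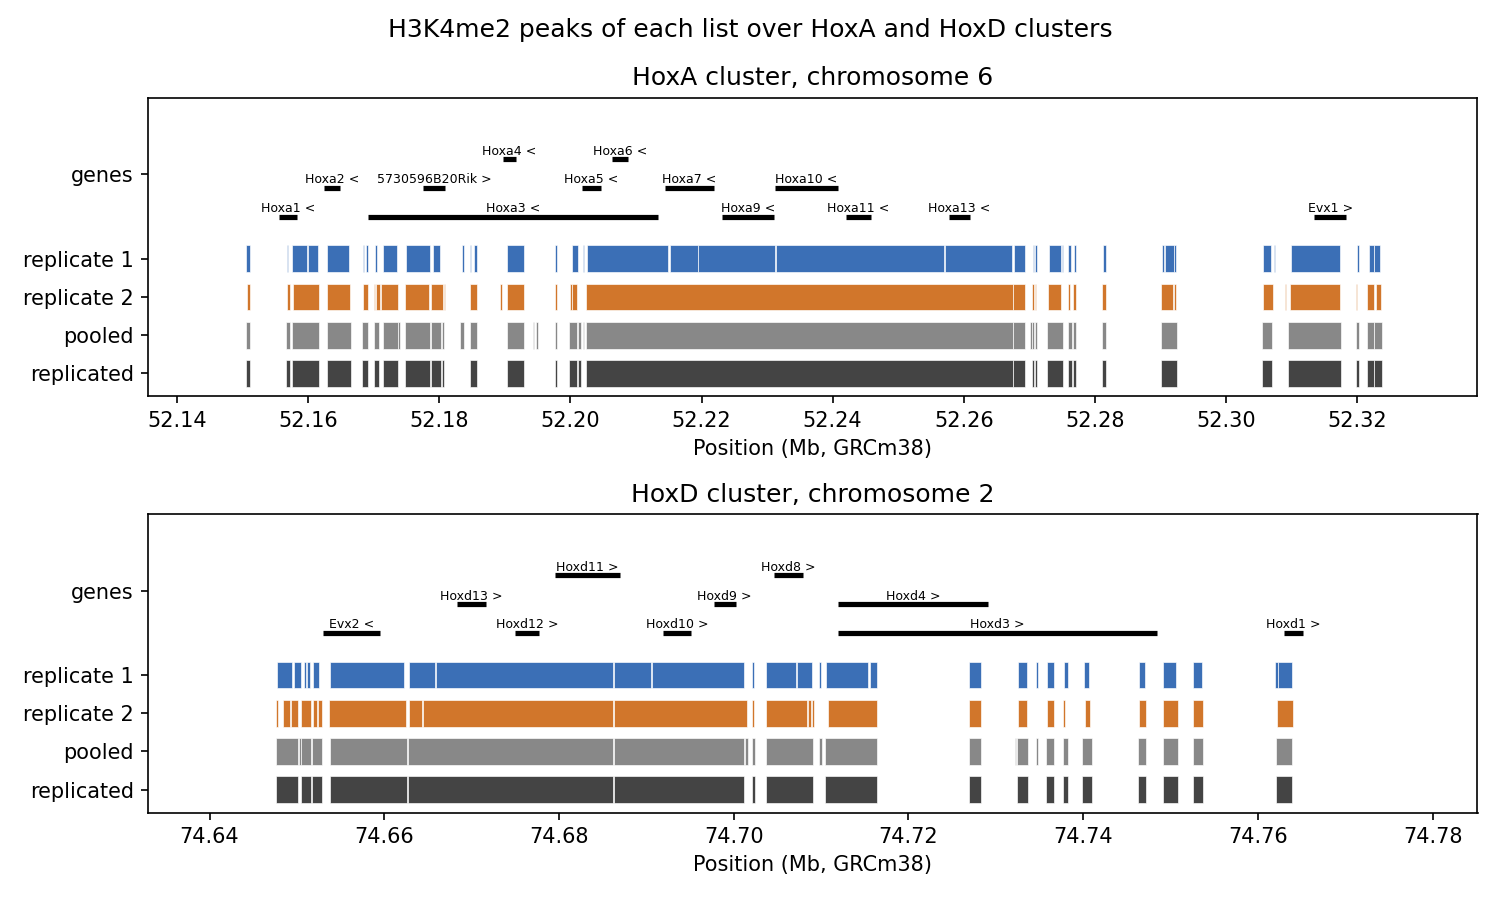
Peaks of the 4 lists (rows) over the HoxA and HoxD clusters with 20 kb on either side, by position (x axis, Mb); black lines are protein-coding genes with their direction, without gene models named Gm. The widest peak of the replicated list, 65066 bp, lies in HoxA, where the widest merged region is 8 peaks in replicate 1 and 4 in replicate 2.

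Distal peaks, the class that holds enhancers but here can also hold starts of non-coding genes, were counted per gene. The gene with most was Zfhx3, which encodes a homeodomain factor, with 58 replicated distal peaks (84.5 ± 2.1 in the libraries' own lists, SD, n = 2). It was followed by Zfp608 with 35 (48.5 ± 0.71), Auts2 with 32 (49.0 ± 5.7), Nr2f2, a nuclear receptor gene, with 32 (40 ± 1.4), Gse1 with 30 (48.5 ± 0.71), Bcor with 30 (40 ± 4.2), Tbx3, a limb patterning gene, with 28 (42.0 ± 4.2), Mecom with 28 (41.5 ± 4.9), Fam92b with 28 (38.0 ± 1.4) and Med13l with 27 (34.0 ± 1.4). Sox9 also had 27 (34.5 ± 4.9). This ranking is not adjusted for domain length, which was 1339 kb for Zfhx3 and 1649 kb for Auts2, but 230 kb for Gse1 and 172 kb for Fam92b. Limb patterning genes had a mean of 8.72 distal peaks (13.0 ± 0.061, SD, n = 2), against a median of 2.04 for random lists of the same domain length. Chondrogenic genes had 4.69 (6.80 ± 0.066) against 1.47, tendon genes 4.66 (7.02 ± 0.22) against 2.07, joint genes 4.55 (6.73 ± 0.39) against 2.14, myogenic genes 3.06 (3.68 ± 0.059) against 1.28, ectoderm genes 2.90 (3.64 ± 0.073) against 1.24 and Hox genes 1.44 (1.99 ± 0.054) against 0.256. These 7 lists had adjusted permutation p from 0.001 to 0.025. For the ectoderm list this was lost with the pooled list (adjusted permutation p = 0.074) and without replicate 2 (adjusted permutation p = 0.052). Liver genes, with 0.265 (0.456 ± 0.10) against 0.912, and chemosensory receptor genes, with 0.0467 (0.0571 ± 0.0049) against 0.459, had fewer (adjusted permutation p = 0.025 and 0.001). The liver call was lost with the pooled list, without replicate 2 and over 10 kb away (adjusted permutation p from 0.055 to 0.11). The other 11 lists, from 0.70 peaks in blood cell genes to 2.91 in Schwann cell and neural crest genes, did not pass the threshold (adjusted permutation p from 0.052 to 1). The cell cycle list passed without either replicate (adjusted permutation p = 0.044 and 0.041). With distal peaks over 10 kb away, the limb patterning, chondrogenic, tendon and Hox lists stayed above, and the joint, myogenic and ectoderm lists had adjusted permutation p from 0.10 to 0.12. With random lists not matched on domain length the Hox list did not pass (adjusted permutation p = 0.36), and the neuronal (adjusted permutation p = 0.033) and Schwann cell and neural crest lists (adjusted permutation p = 0.019) did. Distal peaks are assigned to the nearest start, which need not be the gene they act on.

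Known regulatory landscapes of the limb and comparison loci were measured by the share of bases covered. The interval from Tbx5 to Tbx3, a pair of T-box genes of the limb on chromosome 5 from 119670669 to 119885219, was covered over 26.2% (24.8% ± 0.50, SD, n = 2), 12.8 times the median of matched random windows. The interval of Tbx4, the hindlimb T-box gene, and Tbx2 was covered over 34.9% (34.7% ± 0.28), against 5.06%. The HoxA cluster was covered over 66.1% (63.2% ± 1.8) against 17.3%, and the domain from Pitx1 to Neurog1 over 10.9% (9.94% ± 0.25) against 2.51%. These 4 of the 28 loci passed the threshold, with adjusted permutation p of 0.0056, 0.024, 0.024 and 0.046. The last of them was lost with windows not matched on gene number (adjusted permutation p = 0.15). The HoxD cluster (62.4%, 60.4% ± 0.41, against 19.4%) and the HoxC cluster (58.0%, 53.9% ± 4.3, against 14.3%) did not pass, with adjusted permutation p of 0.097 and 0.057. For both, gene-rich windows are scarce, with 1584 and 5489 random windows, and both passed with windows not matched on gene number (adjusted permutation p = 0.0019). Windows were drawn by length, gaps and gene number, with no rule that kept them off the Hox clusters. The Hox clusters may thus be partly compared with themselves. The HoxC cluster also passed with the pooled list and without replicate 1 (adjusted permutation p = 0.029 and 0.041). The HoxB cluster had 25.6% (21.4% ± 3.4) against 10.6% (adjusted permutation p = 0.12), and passed with windows not matched on gene number (adjusted permutation p = 0.0067).

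Among the long-range domains, the HoxD 5′ landscape had 36 peaks and 7.16% of bases covered (6.35% ± 0.14) against 1.75% (adjusted permutation p = 0.063), and the HoxD 3′ landscape 3.69% (3.33% ± 0.14) against 0.773%. The HoxA 5′ landscape had 4.49% (3.67% ± 0.25) against 1.77%. The Irx3 to Irx5 domain had 4.99% (4.60% ± 0.14) against 1.06%, the Meis2 gene 6.45% (5.85% ± 1.2) against 0.482%, the Gli3 gene 3.33% (3.17% ± 0.23) against 0.561% and the Sox9 upstream desert 1.52% (1.39% ± 0.10) against 0.374%. Coverage was 7.68% in the Fgf8 to Fbxw4 domain, 3.76% from Shox2 to Rsrc1, 2.37% from Grem1 to Fmn1, 2.28% from Runx2 to Supt3 and 10.9% from Fgf3 to Fgf4. The Shh to Lmbr1 domain, which holds the limb enhancer of Shh, had 6 peaks over 922 kb and 1.12% of bases covered (0.985% ± 0.0069), against 1.13% in random windows. None of these domains passed after adjustment (adjusted permutation p from 0.063 to 0.99).

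Of the muscle locus and the comparison loci chosen for other tissues, the interval of Alb and Afp had no peak in the replicated list or in either library's list, and the alpha-globin locus had 6.25% of bases covered (5.22% ± 0.078) against 13.4%. The Myf5 to Myf6 locus had 2.27% (1.66% ± 0.40), the Pou3f4 locus 0.759%, the Neurod1 locus 2.63% and the Sox2 locus 1.19%. The Six6 to Six1 locus, which holds Six1 of the myogenic list, had 14.3% (13.3% ± 0.14) against 4.32%. The Nkx2-1 to Pax9 locus had 10.4% (9.66% ± 0.48) against 3.28%. None of these 8 loci passed after adjustment (adjusted permutation p from 0.097 to 0.87).

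**Figure D5:**
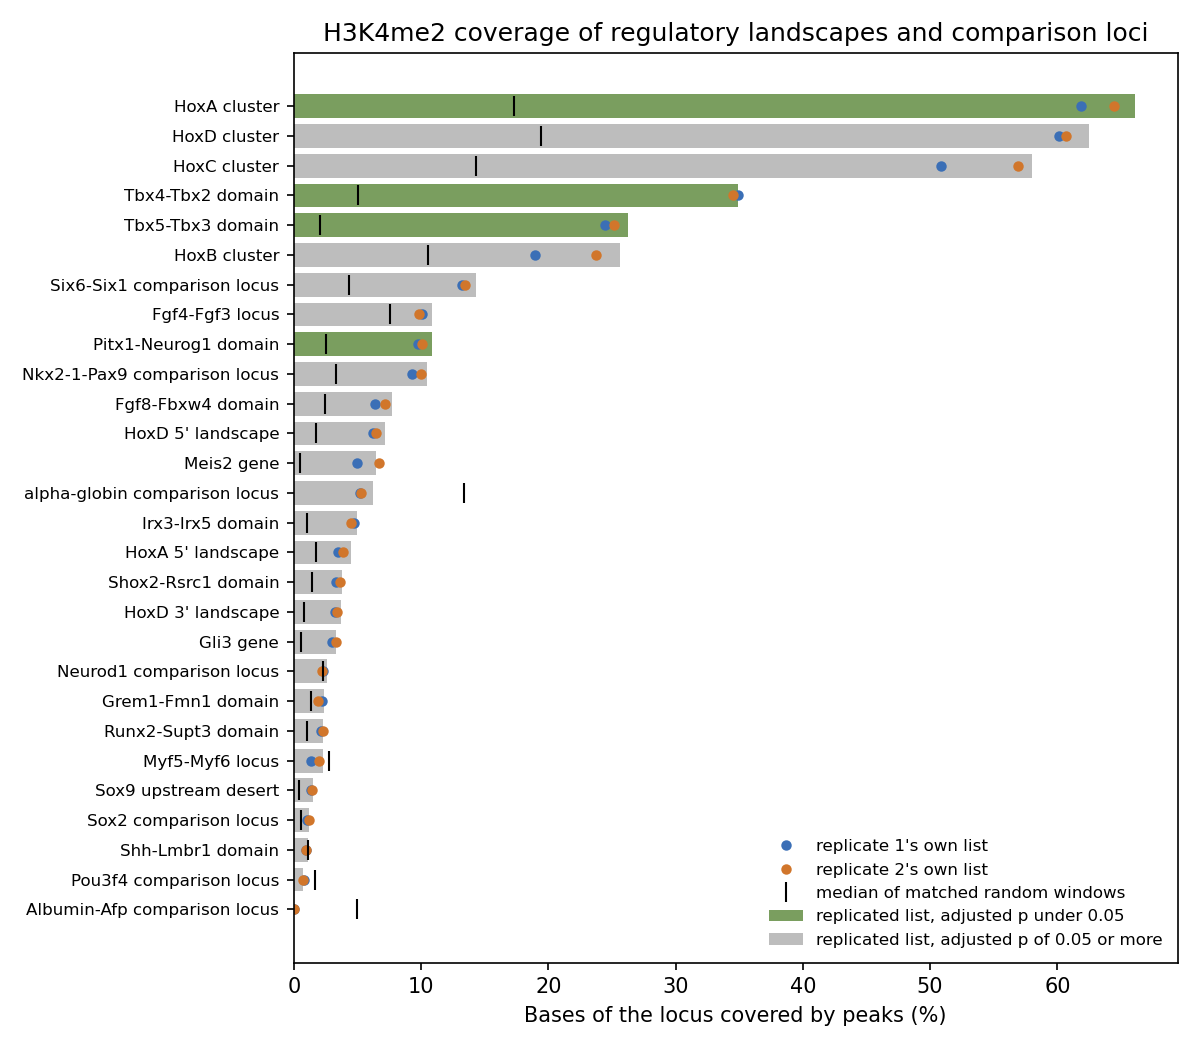
Share of bases covered by peaks (x axis, %) for each of the 28 loci. Bars give the replicated list, in green where the adjusted permutation p is under 0.05, points each library's own list, and black ticks the median of matched random windows. The HoxA cluster has 66.1% and the interval of Tbx5 and Tbx3 26.2%.

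Sequences of distal peaks were searched for 28 consensus motifs. Of 22368 distal peaks, 18485 could be matched on GC content to flanking windows. The consensus of CTCF, which binds at domain borders, was present in 3.93% of peaks and 0.995% of flanks, an odds ratio of 4.07 (3.91 ± 0.48 in the libraries' own lists, SD, n = 2). That of SP and KLF factors had an odds ratio of 2.92 (2.75 ± 0.083) and that of NRF1 2.30 (2.42 ± 0.22), and both hold CpG-rich sequence. Homeodomain consensus sites were in 27.5% of peaks and 18.2% of flanks (odds ratio 1.71, 1.61 ± 0.020), sites of the HOX13 group in 6.62% and 3.82% (odds ratio 1.78, 1.67 ± 0.028) and PBX-HOX sites in 8.74% and 5.50% (odds ratio 1.65, 1.59 ± 0.025). The lowest odds ratios were those of PITX (0.836, 0.861 ± 0.0035), NFY (0.854, 0.864 ± 0.0055) and AP-1 (0.862, 0.873 ± 0.012). In simulated data the PITX consensus passed as less frequent without having been planted, so its value carries little weight. In all, 13 motifs were more frequent in peaks and 6 less frequent past an adjusted 0.05 in Fisher's exact test, and 9 passed in neither direction. The homeodomain, HOX13 and PBX-HOX examples were chosen after their values were seen. These values rest on the GC matching. Without it the odds ratio of homeodomain sites fell to 1.04, that of PBX-HOX to 1.11 and that of HOX13 to 1.35, and FOX sites, at 1.34 with it, turned to 0.931.

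Peaks were sparse on the sex chromosomes. Chromosome X had 5.79 replicated peaks per Mb, against 16.1 on the autosomes, a ratio of 0.360 (0.336 ± 0.0067 in the libraries' own lists, SD, n = 2). Of the protein-coding genes on X 52.2% had a promoter peak, against 68.4% on the autosomes. Chromosome Y held 6 replicated peaks. Both pools were of male and female embryos, and no test was made of these values.

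The libraries were last compared list by list. Every limb patterning, joint, Hox, housekeeping and cell cycle gene had a promoter peak in both. The ectoderm list and the gut and lung list had 3 members each with a promoter peak in replicate 2 only, and 0 in replicate 1 only. No list passed the exact binomial test (smallest unadjusted p = 0.25, adjusted p = 1), and none had an unadjusted p under 0.05. Over all genes 126 were marked in replicate 1 only and 168 in replicate 2 only (exact binomial p = 0.017). At the stricter threshold these were 64 and 140 (exact binomial p = 1.1e-07), where the libraries' lists held 32334 and 34838 peaks. With windows of 2.5 kb they were 153 and 161 (exact binomial p = 0.69). These tests treat genes as independent and compare only these 2 libraries, so they do not measure a difference between pools in general.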

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

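Outside the chromosomes used in the comparisons, 13 replicated peaks lay on unlocalised or unplaced scaffolds of the assembly, which no comparison used. Replicate 1 had 13 such peaks and replicate 2 had 15. In the replicated list 5 of them were on a scaffold assigned to chromosome X, 3 on one assigned to chromosome 4, and 2 on one that is assigned to no chromosome. The highest fold enrichment among them was 15.3, above the median of 10 of the replicated list on the main chromosomes. Gene annotation of these scaffolds was not used here.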

How the results depend on the processing

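Comprehensive transcripts, matching on deciles of CpG content and the settings for chromosome X were chosen after seeing the data. Of 151 alternative values of the summary results, 124 counted as the same. Values with a p-value had to keep their side of the threshold, and their direction if past it. Counts had to stay within 1.5 times the main count, and shares with a Wilson 95% interval inside it. Any other value had to move by no more than the SD of the 2 libraries' values, or of the 2 directions of overlap. For values that changed, the cause was not tested unless the setting itself gives it. With an overlap of 50% of the peak, the weakest decile was shared at 30.2% and the 10000 strongest peaks at 83.9%. The share of pooled peaks kept as replicated was 94.8% at the stricter threshold, which removes weak peaks. Replicate 1 then covered 91.4% and replicate 2 94.8% of the replicated peaks, and 95.1% and 96.8% with 1 bp. The intron share lost its difference from the random share with the pooled list (37.8% against 37.6%) and with promoter windows of 500 bp (37.8% against 38.1%). The share of genes with a promoter peak was 66.9% at the stricter threshold, 68.3% with the pooled list, 66.5% and 68.4% with windows of 500 bp and 2.5 kb, 65.5% with the most 5′ start, 68.2% with comprehensive transcripts and 67.4% to 67.6% leaving out a library. Matching on deciles of CpG content left 4 of 10 lists above background for promoter peaks, and matching on CpG class left 0 of 5 lists below for bases covered. For distal peaks 4 of 7 lists were above beyond 10 kb, and 1 of 2 below beyond 10 kb and with the pooled list, with 1 to 2 leaving out a library. The X ratio was 0.382 at the stricter threshold, 0.291 with the pooled list and 0.331 to 0.341 leaving out a library. Without GC matching the odds ratios of MEIS (1.16), SOX (0.957), GLI (1.21), TFAP2 (1.74) and FOX (0.931) turned, and those of homeodomain and PBX-HOX sites fell from 1.71 to 1.04 and from 1.65 to 1.11. Among the single lists, 192 of 200 values for promoter peaks, 135 of 140 for bases covered, 107 of 120 for distal peaks and 115 of 120 for broad regions stayed on their side of the threshold, as did 134 of 140 for loci. Bases covered at named genes moved by more than the spread between the libraries in 299 of 660 values, and distal peaks in 45 of 50. The overlap of the libraries has no value without one of them. The HNF1 motif gave no finite ratio in several settings and was left out of these counts. No paired analysis was possible because there is 1 group. Read depth is unknown, and its effect on the peaks called, their width and the bases covered was not tested.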

Other observations

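The test on deciles of CpG content was chosen after the result was seen. Germ cell genes were marked less often than random lists of the same promoter composition. Of the 10 germ cell genes with CpG-rich promoters 3 had a promoter peak, and the 7 without one were Mael, Sycp1, Sycp2, Sycp3, Ddx4, Spo11 and Hormad1, genes of meiosis and of the germ line, which were named after their values were seen apart from Ddx4. Genome-wide, 99.1% of CpG-rich promoters were marked. The share of the whole list was 11.8%, against a median of 55.9% for random lists matched on CpG-rich and other promoters (adjusted permutation p = 0.00067) and 64.7% for random lists matched on deciles of CpG content (adjusted permutation p = 0.0013). The liver (14.7% against 32.4%, adjusted permutation p = 0.02), gut and lung (26.7% against 40%, adjusted permutation p = 0.03) and chemosensory lists (0.418% against 9.69%, adjusted permutation p = 0.0013) also lay below on deciles.

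At most of the CpG-rich promoters examined, the highest point of the peak lay on the transcribed side of the most 5′ start. Of 9349 genes whose most 5′ start was inside a replicated peak, 78.1% had the summit downstream of it, at a median of 597 bp. Summits upstream of it had a median offset of −447 bp. A summit at a later start of the same gene also counts as downstream, and genes with a single start were not examined apart. In the libraries' own lists the shares were 76.9% and 77.3%. The summit was within 100 bp of the start in 4.41% of these genes.

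Neuronal promoters, like those of limb patterning genes, were marked more often than those of other genes (94.6% and 100%), though these lists were not tested against each other. The neuronal share was 18.9 percentage points above the median of random lists matched on CpG-rich and other promoters, so that this division alone leaves the excess in place. Against random lists matched on deciles of CpG content the excess was 8.11 points (adjusted permutation p = 0.11), which leaves open that finer differences in CpG content may account for it. Nuclei of neurons in the dissected tissue also stay open, since the distal peaks of the list were at percentile 78.4 of lists of the same domain length, neither high nor low. Apart from these, no biological explanation was tested, as there is 1 group.

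In replicate 1 19.9% and in replicate 2 22.4% of peaks had no counterpart in the other library. Of these, 99.5% lay below the median fold enrichment of their own list, which is consistent with weak calls near the threshold. Pools with different shares of a cell type stay open: with windows of 1 kb and no stricter threshold, at most 3 members of a list were marked in only one library. With so few the exact test cannot go under 0.25. At the stricter threshold the myogenic list had 1 such member in replicate 1 and 4 in replicate 2 (exact binomial p = 0.375). With windows of 2.5 kb the endothelial list had 4 and 2 (exact binomial p = 0.69). The bound set beforehand, at most 3 such members, was met, but it was wrong because no list within it could have passed, and this reading was changed more than once after the value was seen. Apart from these, no biological explanation was tested, as there is 1 group.

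The widest peak, over HoxA, was 65048 bp in replicate 2, while no peak of replicate 1 was wider than 25642 bp. The bases covered in the merged region that holds it differed by a factor of 1.01 between the libraries (67278 and 67708 bp), in 8 peaks in replicate 1 and 4 in replicate 2. Under the widest peak of replicate 2, a peak of replicate 1 ended at 52231278 and the next began at 52231350. These values fit a marked region that was split at more small gaps in replicate 1 than in replicate 2. Widths of single peaks, unlike bases covered, may then say little about differences between the libraries. No biological explanation was tested.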
